A study of Rattus norvegicus with 12 samples.

How the data were processed

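RNA was extracted from liver with Trizol and sequenced from libraries of an NEBNext Ultra kit, per the labels' protocols, in 12 libraries of rat liver in 4 groups (normal, model and 2 didymin dose groups) of 3. The authors deposited 3 tables, each of 6 libraries, that set the normal group and each didymin group against the model. The values used are raw read counts per gene, per the file headers and because they are whole numbers. The aligner, the counting tool, the annotation and any filter are not given in the sources used here, nor is whether counting used strand. The submitters' processing notes name DESeq2 and the build mm9, both without a version. That build is of mouse, while 14408 of the 16558 gene names in the tables equal a current rat symbol and another 747 a synonym of one, and names of rat contigs and of the rat histocompatibility complex are among them, so no coordinates are printed. The authors' deposited tables also hold a log2 fold change, a p-value and an adjusted p-value per gene, which are used only where the authors' deposited table is named. The 36 per-sample columns of other values in the tables were not used.

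The columns name animals by a letter and a number (N.1, M2.1, G.3), which outside the normal group do not follow the replicate numbers in the labels, so columns were matched to groups and not to single samples. N and M were taken as normal and model. D and G are the didymin arms, and no label pairs a letter with the low or the high dose. Rats were divided into groups at random per the labels, and no 2 columns bear the same animal name, but no label ties a library to an animal, so p-values measure the spread between these libraries. M2.1 is named unlike M.5 and M.6. The labels do not say why, or whether it is from another cohort or a repeat. On the first principal component it lay at −53.7, beside the normal libraries N.1 and N.2 at −55.2 and −44.9. These libraries also had the lowest shares of mitochondrial counts (4.90%, 4.63% and 3.85%), so their nearness does not mark M2.1 as normal. In the mean of the cholesterol synthesis genes M2.1, at 4.43 log2 CPM, lay below all normal libraries (5.38 to 6.29). The 3 model libraries stand in all 3 tables, and none of their counts differed between tables. The tables were joined on the gene name into 1 matrix of 16558 genes, with 0 for a gene that a table does not list. Each table lists genes with at least 1 count over its 6 libraries, and no gene missing from a table had a model count above 0 elsewhere. No 2 libraries of a group agreed within sampling noise, with chi-square per degree of freedom between 22.4 and 893.

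Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups, which left 12355, libraries were scaled by TMM, and all 12 libraries entered 1 quasi-likelihood fit with a mean per group, no covariate and 8 residual degrees of freedom. The prior degrees of freedom were 4.32 and the common biological coefficient of variation was 0.409, a wide spread between libraries. The contrasts were the model against normal, each arm against the model, the mean of both arms against the model and against normal, and arm G against arm D. P-values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05. CPM values use the TMM-scaled library sizes. Fold changes are given with a standard error, and group means with an SD over 3 libraries.

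Before the data were examined, 36 gene lists, the rule for naming genes, the tests and the alternatives were fixed. The lists cover lipid, sterol, bile acid, glucose and drug metabolism, stress and inflammation, the clock and the cell cycle, sex-biased genes, and markers of the cell types of liver and of neighbouring tissue. Each list was tested by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with the correlation estimated. fry, which tests whether the genes of a list move one way on balance, was run beside it. P-values of lists were adjusted over the 36 lists. With the estimated correlation no list passed in any comparison. Within a list, genes were also adjusted over the list alone. That adjustment does not extend across the 36 lists or the comparisons, so some single genes would pass it by chance. The rule names genes past the threshold by size of change. Where none passes, it names the 3 per direction with the smallest p. It adds up to 3 members of a described list with the smallest p, and 25 key genes of fatty liver which may be given as counts where they did not pass. It was written for the comparisons of the model and of each arm, and was applied to the other comparisons too. Further members are named where they passed over their list alone. Of the key genes, Il6 and Tnf did not pass the filter on low counts. Some genes that the rule names are not reported here.

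The gene test was checked on simulated counts for 12355 genes with the means and library sizes of these data and 200 changed genes. For model against normal it recovered 10% of 50 genes changed 2-fold, 52% changed 4-fold, 82% changed 8-fold and 96% changed 16-fold. For arm D against the model it recovered 6%, 48%, 88% and 96%, and for arm G 8%, 52%, 84% and 88%. So small changes would mostly be missed with 3 libraries per group. The lowest expressed genes were not among those changed, and each gene was drawn independently, without structure shared by the genes of a library. The recovery of large changes may therefore be too favourable, and in the real data large changes such as that of Tm7sf2 missed the threshold too.

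The alternatives fixed in advance were DESeq2 1.42.0 (Wald test, with and without independent filtering), size factors of DESeq2's kind in edgeR, no filter beyond 1 count, a filter at 1 CPM in at least 3 libraries, a fit of the compared groups alone, limma-voom with sample quality weights, a threshold joined with a 2-fold change, and leaving out each library in turn. A fit with the replicate number as a block was planned and could not be made. After the share of mitochondrial counts was seen, 4 more were added: that share (on the logit scale) as a covariate, leaving out M.6 and G.3 (above 40%), leaving out M.6, G.3, M.5 and D.1 (above 15%), which leaves M2.1 as the only model library, and testing nuclear-coded genes alone. Correlations over the 12 libraries were tested with 100000 permutations, two-sided. The covariance of fold changes between comparisons that share the model group was set beside 100 simulations of unchanged arms.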

Results

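Liver transcriptomes were measured by RNA sequencing in Sprague Dawley rats, an outbred laboratory stock, in 4 groups of 3 libraries each. The normal group received saline in place of treatment, and the model group was kept on a high-fat diet for 8 weeks, which is used to bring about fatty liver. The other 2 groups received didymin, a flavonoid glycoside of citrus fruit, on top of the high-fat diet, at different doses. The count columns letter these groups D and G without saying which had the lower dose, so they are called arm D and arm G here. No dose is printed for either arm.

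Total counts per library ran from 12469914 to 15521648, and between 13582 and 14591 genes had at least 1 count. The 13 genes of the mitochondrial genome took a share of the counts that differed widely between libraries of one group. It was 4.63%, 3.85% and 11.2% in the normal libraries N.1, N.2 and N.3, and 18.8%, 44.1% and 4.90% in the model libraries M.5, M.6 and M2.1. In arm D it was 16.02%, 5.62% and 5.88% in D.1, D.4 and D.7, and in arm G it was 6.07%, 61.0% and 7.88% in G.1, G.3 and G.4. The first principal component of the log2 CPM (scaled count) values held 44.3% of the variance. M.6 and G.3 lay at its positive end, at 70.8 and 97.4, and N.1 and M2.1 at its negative end, at −55.2 and −53.7. Nuclear-coded counts were 4869054 in G.3 and 7173229 in M.6, against 10887482 to 14761817 in the other 10 libraries, so values of low genes are least precise in those libraries.

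**Figure D1:**
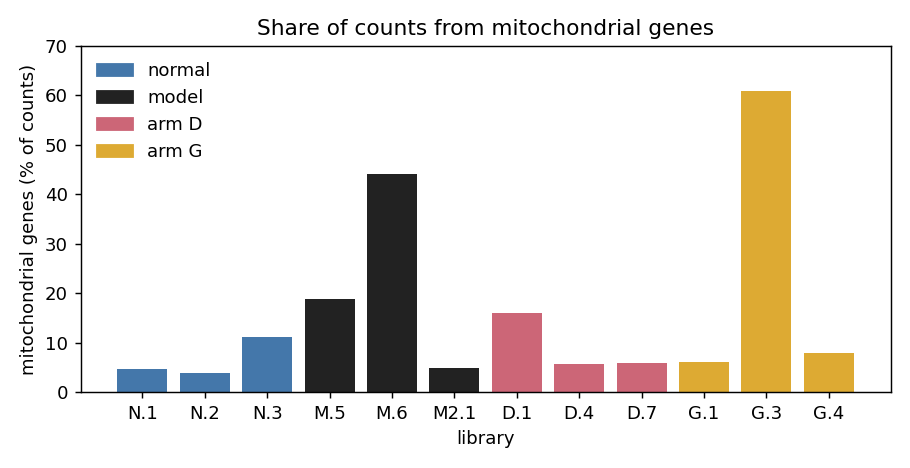
Share of all counts, in percent, that came from the 13 mitochondrial genes, as 1 bar for each of the 12 libraries, coloured by group. G.3 at 61.0% and M.6 at 44.1% stand above all other libraries, of which the highest is M.5 at 18.8%.

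The model was compared with the normal group to ask what the high-fat diet did to the liver transcriptome. Genes of cholesterol synthesis were lower in the model. Of the 26 measured members of the cholesterol synthesis and uptake list, 25 had a negative log2 fold change, with a median of −1.68, and 18 fell when adjusted over the list alone. Tm7sf2, a sterol reductase, was at 116 ± 34.4 CPM in the normal and 8.10 ± 3.04 CPM in the model libraries (SD, n = 3), a log2 fold change of −3.83 ± 0.58 (SE). Sqle, the squalene epoxidase, was at 37.2 ± 21.6 and 2.94 ± 1.001 CPM, a log2 fold change of −3.66 ± 0.58. Fdps, which makes farnesyl diphosphate, had −2.03 ± 0.32. All 3 passed when adjusted over the list alone, and none passed over all 12355 genes. In camera, which sets a list against all other genes, the list was lower with an adjusted p of 1.86e-29. The adjusted p was 0.105 with an estimated correlation between its genes, and fry, which asks only whether the genes move one way, gave an adjusted p of 0.0184. The normal library N.3, with the highest mitochondrial share of its group, also had the lowest mean of this list in that group, at 5.38 log2 CPM against 5.95 and 6.29. The model libraries lay between 3.89 and 4.43.

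Genes that make and desaturate fatty acids did not move as a group in the model (camera adjusted p = 0.0919, 21 measured, 14 of them negative). Single members passed when adjusted over the list alone, in both directions. Scd, the stearoyl-CoA desaturase, rose by a log2 fold change of 3.22 ± 0.84, while Fads1, a fatty acid desaturase of long chains, fell by 2.45 ± 0.64 and Acss2, which activates acetate, fell by 1.26 ± 0.34. The model libraries were far apart in Scd, at 904 ± 801 CPM (SD, n = 3), and M.6 at 54.0 CPM lay below all normal libraries. The lipogenic regulator Srebf1 had a log2 fold change of 2.20 ± 0.74 and Mlxipl, a glucose-responsive regulator, had 1.05 ± 0.43, both short of the threshold over the list. Fasn, the fatty acid synthase, had −0.37 ± 0.47, which turned to 0.02 without M.6. In the list of gluconeogenesis, glycolysis and insulin response no member passed. Among its members were Ppargc1a, a coactivator of gluconeogenesis, at −2.57 ± 0.66 and Pck1, a gluconeogenic enzyme, at −1.15 ± 0.51.

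In bile acid metabolism, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 31.2 ± 10.1 to 119 ± 74.1 CPM (SD, n = 3), a log2 fold change of 1.93 ± 0.46, and was the 1 of 21 members to pass when adjusted over the list alone. Abcg8, which exports sterols into bile, had −1.35 ± 0.45 and did not pass. Among 8 genes that differ between male and female rat liver, 3 fell when adjusted over the list alone. They were Prlr, the prolactin receptor, at −4.40 ± 0.97, Cyp2c12, a steroid-metabolising enzyme of female rats, at −2.71 ± 0.44, and Srd5a1, a steroid reductase, at −1.39 ± 0.45. Cyp2c12 belongs to a family of similar genes whose reads can be split in counting, so its value is uncertain. The list was lower in camera (adjusted p = 0.000117), with an adjusted p of 0.245 with an estimated correlation. It was not divided by the sex in which its genes are higher, so this shift does not show a move towards either sex. Lox, which cross-links collagen, rose by 2.79 ± 0.67 as the only 1 of 29 extracellular matrix genes to pass over the list alone, and Col1a1 had −0.32 ± 0.50. The sign of Col1a1 turned with limma-voom, to 0.46, and without N.3, to 0.39.

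The cell cycle list was higher in the model in camera (adjusted p = 1.39e-05), with a median log2 fold change of 0.80 and 20 of 24 members positive. Its adjusted p was 0.610 with an estimated correlation. Ccnd1, a cyclin of entry into the cycle, rose by 1.27 ± 0.29 and passed over the list alone, while Top2a at 1.67 ± 0.58 and Cdk1 at 2.23 ± 0.88, both used in division, did not. Lists of hepatocyte and endothelial genes were lower. Medians were −0.71 for acute phase proteins (16 of 19 negative, for example Itih3 at −0.74 ± 0.34), −0.53 for hepatocyte markers (17 of 17 negative) and −0.60 for periportal hepatocyte markers (9 of 13 negative), such as Hal at −1.10 ± 0.44 and Ass1 at −0.87 ± 0.37, enzymes of histidine and urea metabolism. Fatty acid oxidation and PPAR-alpha targets had a median of −0.29 with 22 of 31 negative, with Creb3l3, a regulator of fasting metabolism, at −0.83 ± 0.25 and Cpt1a, which carries fatty acids into mitochondria, at −0.74 ± 0.49. Sinusoidal endothelial markers had −0.30 with 13 of 15 negative. Of the model libraries only M.6, at a periportal mean of 6.71 log2 CPM, lay below the normal ones (7.75 to 8.13), with M.5 at 7.82 and M2.1 at 7.99. No member of these 5 lists passed over its list alone, and their adjusted p in camera ran from 1.43e-05 to 0.0150, and was 0.610 or 0.695 with an estimated correlation. The acute phase and hepatocyte means fell with the mitochondrial share over the 12 libraries (r = −0.81 and −0.88, adjusted permutation p = 0.0112 and 0.00942 over 7 relations; rho = −0.59 and −0.45, adjusted p = 0.102 and 0.209). They rest on G.3 and M.6, without which r was −0.16 and −0.20.

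Over all 12355 genes, no gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test of model against normal. At an unadjusted p under 0.05 there were 607 genes, 372 higher and 235 lower, where chance alone would give 618. That count fell to 353, 329 and 285 without M.6, N.1 and N.2 and rose to 1233 and 2561 without G.3 and M2.1, and it was 3585 in limma-voom. DESeq2 called 41 genes and limma-voom with sample quality weights called 6, and the authors' deposited table lists 53. The 3 genes per direction with the smallest p missed the threshold. Apart from Tm7sf2, Sqle and Fdps, these were Tmem150c, a membrane protein, at 1.46 ± 0.23, Tex13b at 3.75 ± 0.60 and Adam8, a metalloproteinase, at 3.35 ± 0.62. The adjusted p was 0.0805 for all but Adam8, at 0.201. Without M.6 edgeR called 1 gene and without G.3 it called 6.

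**Figure D2:**
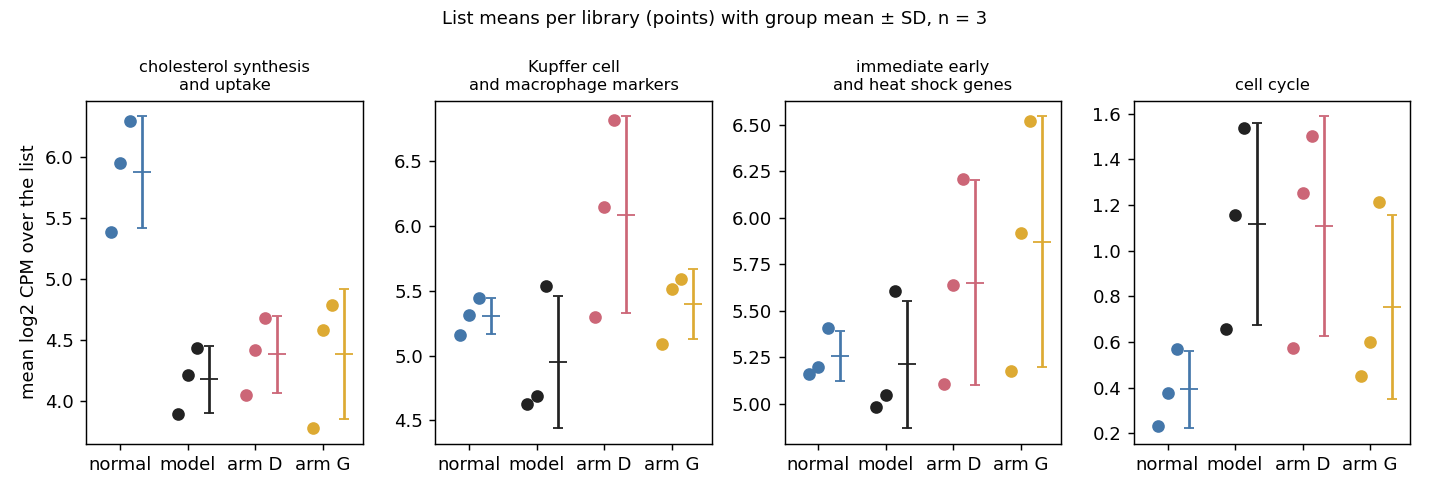
Mean log2 CPM over the members of 4 gene lists in each library (points), by group, with the group mean and its SD (n = 3) beside them. For cholesterol synthesis and uptake the 9 libraries from rats on high-fat diet lie between 3.78 and 4.79, all below the 3 normal libraries at 5.38 to 6.29; in the Kupffer cell list, D.4 at 6.81 and D.7 at 6.15 lie above all others.

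Arm D was compared with the model to ask what didymin changed on the high-fat diet. Markers of Kupffer cells, the resident macrophages of the liver, were higher in arm D. All 17 measured members had a positive log2 fold change, with a median of 1.19 (0.74 without D.4), and 9 rose when adjusted over the list alone. Csf1r, the receptor for macrophage colony-stimulating factor, was at 40.4 ± 8.34 CPM in the model and 110 ± 53.6 CPM in arm D (SD, n = 3), a log2 fold change of 1.45 ± 0.39. Adgre1, which encodes the F4/80 surface marker, rose by 1.43 ± 0.43 and C1qb, a complement component made by macrophages, rose by 1.54 ± 0.51. The list was higher in camera with an adjusted p of 2.29e-10, and the adjusted p was 0.397 with an estimated correlation. D.1 did not share the higher level. Its list mean of 5.30 log2 CPM lay below that of the model library M.5 at 5.54, while D.4 and D.7 were at 6.81 and 6.15. The count of 9 members ended at 0 without D.4, D.7, M2.1 or M.6 in turn and at 0 without both M.6 and G.3, the libraries of highest mitochondrial share. It was 3 in a fit of the 2 groups alone.

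Inflammatory genes were also higher in arm D as lists, with no member past the threshold over its list alone. The list of Toll-like receptor 4, NF-kB and inflammatory cytokines had a median of 0.61 with 28 of 31 members positive, led by Tlr2, a pattern receptor, at 1.72 ± 0.50, Nlrp3, the inflammasome sensor, at 1.64 ± 0.49, and the chemokine Cxcl10 at 1.48 ± 0.50. Tlr4 itself had 1.16 ± 0.58. Interferon response genes had a median of 0.44 with 25 of 31 positive, for example Gbp5 at 1.64 ± 0.55. T and NK cell markers had 0.74 with 14 of 18 positive, including Cd4 at 1.76 ± 0.63, which rat macrophages also express. Acute phase proteins had 0.66 with 19 of 19 positive, for example Lbp at 1.35 ± 0.52. Over the 12 libraries this list fell with the mitochondrial share through G.3 and M.6, and its mean was lowest of the 2 groups in M.6, at 8.91 log2 CPM, against 9.79 in M.5, 9.33 in M2.1 and 9.89 in D.1. Of 15 sinusoidal endothelial markers 14 were positive with a median of 0.63, and Dnase1l3 rose by 1.21 ± 0.31, adjusted over the list alone, while Cdh5, an adhesion protein of endothelium, had 0.82 ± 0.27. Arm D and the model overlapped in the library means of the inflammatory, interferon and T cell lists. D.1 had an interferon mean of 3.43 log2 CPM, below all 3 model libraries (3.46 to 4.29), and an inflammatory mean of 3.15, below M.5 at 3.16. In T and NK cell markers M.5 at 1.83 lay above all 3 arm D libraries (1.70 to 1.78). In camera the adjusted p of these 5 lists ran from 1.82e-07 to 0.00466, and from 0.397 to 0.845 with an estimated correlation.

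Clock genes moved in both directions in arm D. Nr1d1, a repressor of the circadian clock, rose from 7.88 ± 6.13 to 38.3 ± 5.19 CPM (SD, n = 3), a log2 fold change of 2.27 ± 0.55, and Dbp, a clock output factor, rose by 1.33 ± 0.39. Npas2, which Nr1d1 represses, fell by 1.17 ± 0.33, and Noct, a rhythmic deadenylase-like protein, fell by 2.26. These 4 of 18 members passed when adjusted over the list alone. The list as a whole did not differ in camera (adjusted p = 0.334), which looks for a shift one way and can miss opposed changes. A difference in time of sampling between arm D and the model was not tested and stays open beside didymin. Hsd17b2, a steroid dehydrogenase, rose by 0.94 ± 0.28 over its list of 8 sex-biased genes. Immediate early and heat shock genes had a median of 0.26 and an adjusted p of 0.0155 in camera, and 0.845 with an estimated correlation. Their leading members, Junb at 1.30 ± 0.35, Fos at 2.08 ± 0.63 and Btg2 at 1.44 ± 0.46, did not pass.

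The lipogenic genes Mlxipl, Srebf1 and Scd had −1.49 ± 0.44, −1.19 ± 0.72 and −1.17 ± 0.78 in arm D, and none of these 3 passed over the list. Srebf1 turned to 0.11 without M2.1. The higher values of these lipogenic genes in the model against normal came from the same model libraries, so the lower values in arm D are not independent of them. The antioxidant enzyme Hmox1 had 0.80 ± 0.34. The cholesterol list did not pass against the model (median 0.14, camera adjusted p = 0.421), with Tm7sf2 at 1.53 ± 0.54, and a small rise of the list is not excluded.

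In edgeR no gene passed for arm D against the model. At an unadjusted p under 0.05 there were 776 genes, 376 higher and 400 lower, where chance would give 618. That count was 318, 406 and 473 without D.4, M.6 and D.7 and 1429 and 1802 without G.3 and M2.1. DESeq2 called 14, limma-voom called 0, with 2479 genes at an unadjusted p under 0.05, and the authors' deposited table lists 7, among them Nr1d1. The leading genes, which missed the threshold with an adjusted p of 0.783, were Gfra3, a co-receptor for artemin, at 1.66 ± 0.33, the uncharacterised locus LOC102546864 at 2.84 ± 0.63 and Pla1a, a phospholipase, at 1.29 ± 0.29. In the other direction they were Lonrf3 at −1.96 ± 0.40, Eml5, a microtubule-associated protein, at −1.76 ± 0.37 and the zinc finger gene Zfp612 at −2.01 ± 0.45.

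Arm G was compared with the model to ask the same of the other dose. Immediate early genes, which cells switch on within minutes of a stimulus, were higher in arm G. Of 21 measured members of the immediate early and heat shock list 14 were positive, with a median log2 fold change of 0.77, and 5 rose when adjusted over the list alone. Junb, a subunit of the AP-1 transcription factor, was at 73.4 ± 30.1 CPM in the model and 243 ± 80.9 CPM in arm G (SD, n = 3), a log2 fold change of 1.73 ± 0.35. Btg2, an antiproliferative gene, rose by 1.84 ± 0.47 and Fos, another AP-1 subunit, by 1.94 ± 0.63, and the other 2 were Egr1 at 1.34 and Ier3 at 0.90. None of the 5 is a heat shock gene. The adjusted p in camera was 7.25e-06, and 0.688 with an estimated correlation. The list mean was 6.52 log2 CPM in G.1, 5.92 in G.3 and 5.18 in G.4, of which the last lay below the model library M.6 at 5.61. The median was 0.14 without G.1, 0.30 without M2.1 and 0.40 without M.5. The count of 5 was 0 in a fit of the 2 groups alone, 0 without M.5, 1 without M.6 or G.1, and 2 without G.3 and M.6 together.

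Lymphocyte and interferon genes were higher in arm G as lists, with no member past its list. B and plasma cell markers had a median of 0.91 with 9 of 9 positive. T and NK cell markers had 0.47 with 15 of 18 positive, including Cd3e at 1.53 ± 0.67 and Cd27 at 2.22 ± 1.01, and interferon response genes had 0.45 with 27 of 31 positive. The inflammatory list had 0.28 with 25 of 31 positive, led by the neutrophil chemokine Cxcl1 at 2.25 ± 0.62 and Socs3, a brake on cytokine signalling, at 1.79 ± 0.61. Kupffer cell markers had 0.45 with 15 of 17 positive, with the scavenger receptor Marco at 1.89 ± 0.88, and periportal markers had 0.40 with 10 of 13 positive, with Hal at 1.23 ± 0.44. Neutrophil markers had 0.20 over 5 genes. Lower as lists were the cell cycle (median −0.55, 16 of 24 negative, with Ccnd1 at −1.04 ± 0.28 and Cdc20 at −1.36 ± 0.62) and nuclear-coded oxidative phosphorylation (−0.22, 36 of 45 negative). Arm G and the model overlapped in the library means of these lists, apart from the B cell and inflammatory ones. G.3, the library of highest mitochondrial share, had the highest means of all 12 in T and NK cell markers (2.20) and in B and plasma cell markers (2.45). In the former G.1 at 1.19 lay below M.5 at 1.83, and M2.1 was lowest at 0.39. The periportal means of arm G, 7.75 to 7.99, lay level with M.5 at 7.82 and M2.1 at 7.99, and above M.6 alone at 6.71. The lower oxidative phosphorylation rests on G.3, at 6.12, since G.1 at 6.72 and G.4 at 6.70 lay within the model's 6.25 to 7.11. The adjusted p in camera of these 9 lists ran from 7.25e-06 to 0.0497, and from 0.688 to 0.874 with an estimated correlation.

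Lox fell in arm G by 2.66 ± 0.66, from 78.6 ± 55.0 to 12.4 ± 7.17 CPM (SD, n = 3), the only extracellular matrix gene of 29 to pass when adjusted over the list alone. Scd had −2.64 ± 0.82 and Srebf1 −1.02 ± 0.71, without passing over their lists, and Srebf1 turned to 0.27 without M2.1. The higher values of Lox, Scd and Srebf1 in the model against normal came from the same model libraries. The lower values in arm G are therefore not independent of them and do not by themselves show a reversal. Nqo1, an antioxidant enzyme, had 1.65 ± 0.91. The cholesterol list did not pass against the model (median 0.27, camera adjusted p = 0.0703), with Tm7sf2 at 1.57 ± 0.54. A small rise of the list is not excluded.

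In edgeR no gene passed for arm G against the model, and 287 genes, 148 higher and 139 lower, had an unadjusted p under 0.05, where chance would give 618. That count was 921 without G.3, 814 without M2.1 and 110 in a fit of the 2 groups alone. It was 678 with the mitochondrial share as a covariate and 584 without both M.6 and G.3. DESeq2 called 5, limma-voom called 0, with 1584 genes at an unadjusted p under 0.05, and the authors' deposited table lists 1, Marveld1. The leading genes, with an adjusted p of 0.9997, were Junb, the transcriptional repressor Bcl6 at 1.85 ± 0.39 and Sema7a, a semaphorin, at 5.32 ± 1.19. Sema7a had no count in 2 of the 3 model libraries and 0.09 CPM in M.6, so its fold change depends on the prior count. In the other direction they were the zinc finger gene Zfp354a at −2.13 ± 0.44, Eml5 at −1.67 ± 0.37 and the unnamed locus Rn50_5_0815.11 at −2.56 ± 0.59.

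Both arms together were set against the model to estimate the average effect of didymin. Eml5, at −1.71 ± 0.30, and Zfp354a, at −2.03 ± 0.35, had the smallest p, with an adjusted p of 0.510. They were followed by Fam222a at −2.52 ± 0.55, Gfra3 at 1.48 ± 0.30, Junb at 1.51 ± 0.32 and Pla1a at 1.17 ± 0.26, with an adjusted p of 0.995. Scd had −1.90 ± 0.64. When adjusted over the list alone, 6 immediate early genes rose, Junb among them, and Nr1d1 rose while Npas2 and Lox fell. In camera 10 lists passed, led by Kupffer cell markers with a median of 0.79 and 17 of 17 positive (adjusted p = 4.83e-08, and 0.570 with an estimated correlation). In the mean of that list D.1, G.1 and G.3, at 5.30, 5.51 and 5.09 log2 CPM, lay below the model library M.5 at 5.54. G.4 at 5.59 was level with M.5, and D.4 and D.7 were at 6.81 and 6.15. The model libraries M.6 at 4.62 and M2.1 at 4.69 lay below all didymin libraries. No gene passed in edgeR, 569 had an unadjusted p under 0.05 (358, 1446 and 1605 without D.4, M2.1 and G.3, and 2255 in limma-voom), DESeq2 called 6 and limma-voom called 0.

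The arms were also compared with each other. Bcl6 was higher in arm G, at 56.4 ± 25.9 CPM against 7.49 ± 1.51 CPM in arm D (SD, n = 3), a log2 fold change of 2.91 ± 0.40. It missed the threshold over all genes in edgeR (adjusted p = 0.114). It passed without the filter on low counts (adjusted p = 0.0402), without G.4 (adjusted p = 0.00765) and in DESeq2. In other settings it was far from passing: the smallest adjusted p of any gene in edgeR was 0.997 in a fit of these groups alone, 0.9998 without D.7 and 0.936 without D.1. Hsd17b2 was lower in arm G by −1.45 ± 0.29 and Prlr higher by 3.93 ± 1.01, and both passed over the list of sex-biased genes alone. Gfra1, a receptor for glial cell line-derived factor, had −3.45 ± 0.71, Gpm6a −2.73 ± 0.65 and Lonrf3 1.74 ± 0.40, without passing. Kupffer cell markers were lower in arm G than in arm D as a list (median −0.75, 17 of 17 negative, camera adjusted p = 5.16e-06). The adjusted p was 0.946 with an estimated correlation, and no member passed over the list alone, with Adgre1 at −1.29 ± 0.43 and Csf1r at −0.92 ± 0.38. The arms overlapped in the mean of this list. D.1 at 5.30 log2 CPM lay below G.1 at 5.51 and G.4 at 5.59, with G.3 at 5.09, while D.4 and D.7 were at 6.81 and 6.15. No gene passed in edgeR, 423 had an unadjusted p under 0.05, DESeq2 called 5 and limma-voom called 0. The 423 became 157, 187 and 199 without D.4, G.3 and D.7, 889 and 911 without G.1 and G.4, and 931 in limma-voom.

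Both arms were compared with the normal group, which leaves the model libraries out of the contrast. The cholesterol list was lower in the arms too. All 26 members were negative, with a median of −1.45, and 19 fell when adjusted over the list alone, among them Idi1, an isomerase of the pathway, at −2.67 ± 0.37, Sqle at −2.88 ± 0.44 and Fdps at −1.59 ± 0.26. The adjusted p in camera was 2.6e-30, and 0.0970 with an estimated correlation, and fry gave 0.0154. Bile acid and sterol genes passed over their list in both directions. Cyp7a1 rose by 1.87 ± 0.42 and Cyp7b1, of the alternative pathway, by 1.66 ± 0.43, while Abcg8 fell by 2.21 ± 0.38, and Abcg5, Amacr and Abcb11 fell as well. Of 21 lipogenic genes 5 fell, including Acss2 by 1.29 ± 0.28 and Acly, which makes cytosolic acetyl-CoA, by 1.28 ± 0.35. Ighm, the heavy chain of immunoglobulin M, rose by 2.31 ± 0.53 and Jchain by 1.99 ± 0.60, with reads of immunoglobulin genes subject to sharing between similar segments. Prlr fell by 3.98 ± 0.74 and Cyp2c12 by 1.73 ± 0.34.

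Outside the lists, Onecut1, a hepatocyte transcription factor, had −3.78 ± 0.60 in both arms against normal, Tex13b 3.22 ± 0.56, Tmem150c 1.46 ± 0.21 and the tubulin gene Tuba3b 2.51 ± 0.45. The smallest adjusted p of this comparison in edgeR was 0.0726, for Idi1 and Tmem150c, so no gene passed, and 883 genes had an unadjusted p under 0.05 (458 and 426 without N.1 and N.2, and 3088 in limma-voom). DESeq2 called 93 genes and limma-voom 651, and edgeR called 11 when fitted to these groups alone. Onecut1 was at 4.85 CPM in N.3, against 48.0 and 56.1 CPM in the other normal libraries.

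**Figure D3:**
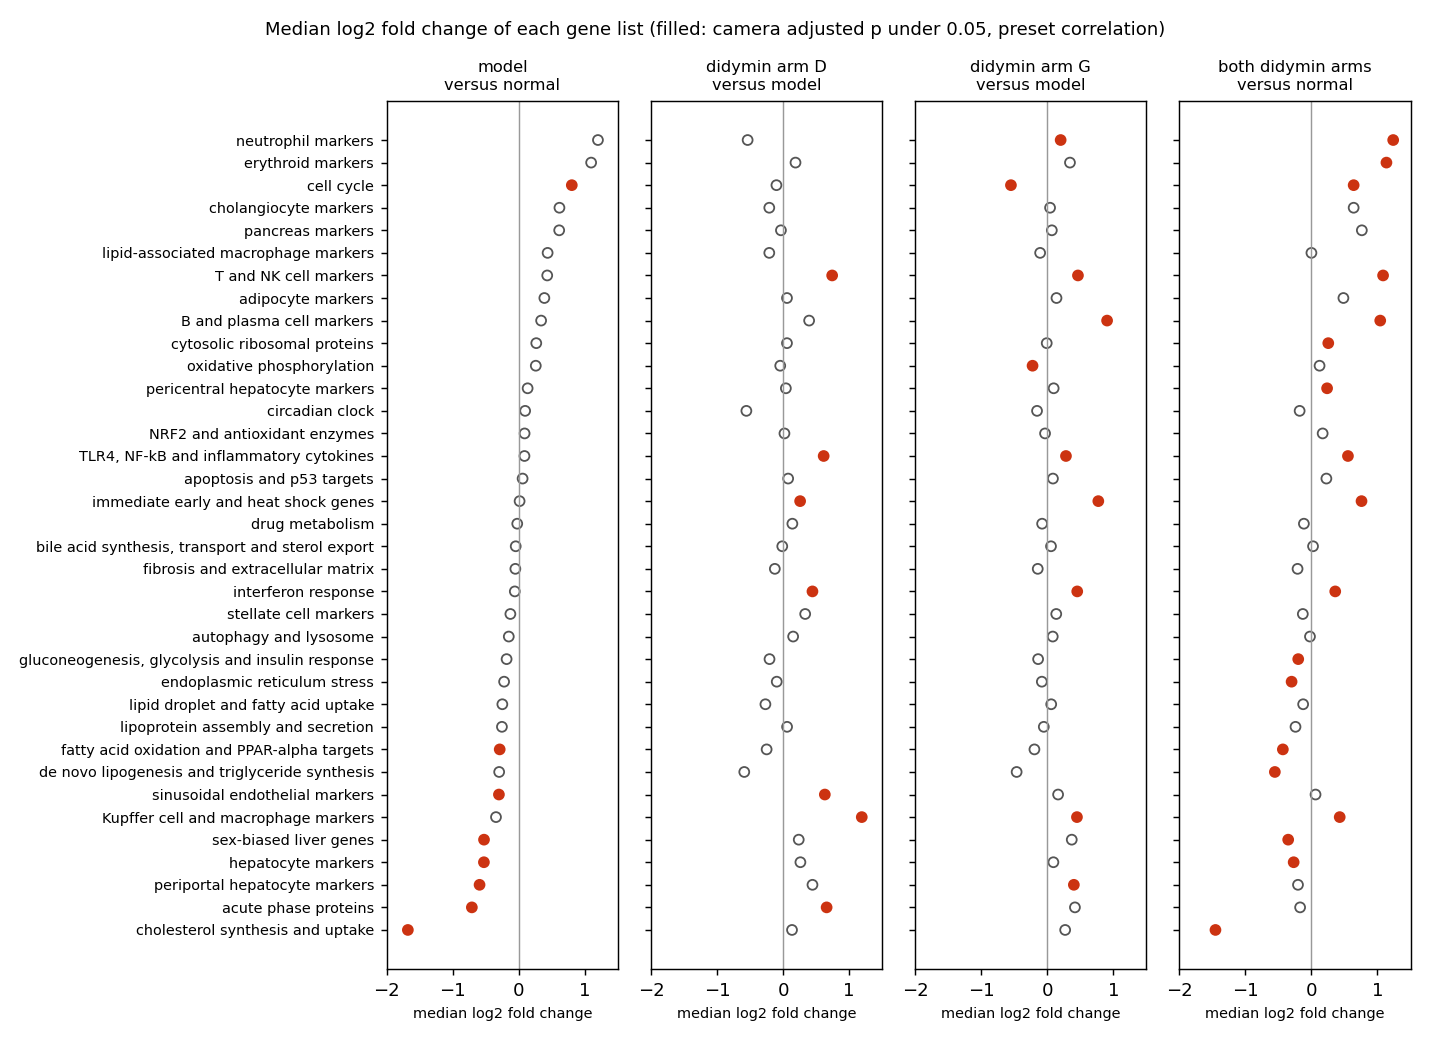
Median log2 fold change of each of the 36 gene lists (horizontal axis, log2 scale) in 4 comparisons, ordered by the value in model versus normal; filled points passed an adjusted p of 0.05 in camera with the preset correlation. The cholesterol list lies far to the left in model versus normal (−1.68) and in both arms versus normal (−1.45), and near 0 in arm D (0.14) and arm G (0.27) versus model.

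Whether didymin turned back the changes of the model was tested by the covariance of fold changes over all 12355 genes, since no gene was called for model against normal. Both comparisons use the model libraries, which alone makes the covariance negative. For arm D it was −0.177, beside −0.140 on average in 100 simulations of an unchanged arm (−0.153 to −0.129), a difference of −0.04. For arm G it was −0.09, beside −0.141 (−0.153 to −0.132), a difference of 0.05. The values lay outside the simulated ranges on opposite sides. Genes were drawn independently in the simulations, so these ranges leave out structure shared by the genes of a library. The difference depended on single model libraries. For arm D it became 0.10 without M.6, 0.004 without M.5 and −0.35 without M2.1, and for arm G 0.12, 0.10 and −0.21 in the same order. In the simulations the shared libraries alone gave most of the arm D covariance and more than that of arm G. With all libraries the covariance of arm G thus gave no sign of reversal beyond the sharing. It cannot exclude one, because the simulations leave out that shared structure. Without M.6 and G.3 the covariance difference of arm G was 0.008. The correlation of the same fold changes was then −0.556, beside −0.398 on average in the simulations. For neither arm did the sign of the difference hold when each model library was left out in turn. The model group of 3 was not split.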

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

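The tests of the cholesterol list and of the Kupffer cell list in this part were chosen after those results were seen, while the test of the oxidative phosphorylation list and the counts of splits were set before their values were known.

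Arm G library G.3 lay apart from the other 5 didymin libraries by Dixon's criterion in 5 library measures. Its total of 12469914 counts and its 13582 detected genes were the lowest of the 6. Its mitochondrial share of 61.0% was the highest. Albumin took 4.42% of its nuclear-coded counts and the 10 leading genes took 13.3%, both the lowest of the 6. Chance marks about 1 in 20 such groups, and these measures depend on each other.

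Between the arms, 4 lists differed in camera on the contrast of arm G against arm D itself. The medians on the log2 scale were −0.75 for Kupffer cell markers, −0.32 for sinusoidal endothelial markers, −0.29 for the inflammatory list and −0.16 for acute phase proteins. None of them passed with an estimated correlation (adjusted p = 0.946), and all 10 splits of the 6 libraries gave at least 4 lists. Without G.3 the count of lists was 14 and without D.4 it was 2.

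The mitochondrial share of the counts ran from 3.85% to 61.0%. The libraries above 15% (M.5, M.6, D.1 and G.3) were all from rats on the high-fat diet, and the highest normal library was N.3 at 11.2%. The share was thus uneven between normal and the other groups. Each of those groups also held a library of low share (M2.1 at 4.90%, D.4 at 5.62% and G.1 at 6.07%), so group alone does not account for it. No biological explanation by group was tested. With more mitochondria per cell, nuclear-coded oxidative phosphorylation genes would rise with the share, and Spearman's rho over the 12 libraries was 0.364 (permutation p = 0.245, adjusted p = 0.286 over 7 relations). Pearson's r was 0.06 over all libraries and 0.925 without G.3 and M.6, so its size depends on those libraries. The list was not high in them: G.3 had the lowest mean of all 12, at 6.12 log2 CPM, and M.6 at 6.60 lay within the range of the others. More mitochondria per cell therefore stays open as a candidate explanation only among the other libraries. There, cytosolic ribosomal protein genes went with the share as well (r = 0.878 without G.3 and M.6). The albumin share of the nuclear-coded counts went the other way (r = −0.84, adjusted permutation p = 0.00942; rho = −0.57, adjusted p = 0.102), and r was −0.20 without G.3 and M.6. Loss of cytosolic RNA in those 2 libraries is a candidate explanation that could not be tested. The planned test used transcripts retained in the nucleus, such as Malat1, and none of them was among the genes tested.

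The cholesterol synthesis list was lower in the model than in normal (median −1.68), and the tables argue against 2 technical causes as the whole explanation. With the mitochondrial share as a covariate the median was −1.23, with 17 members lower over the list alone. Against a lower share of hepatocyte RNA, the list mean less the hepatocyte marker mean was itself lower in the model by −1.19 ± 0.30 (SE). The list was lower in both arms against normal too, at a median of −1.45. An effect of the high-fat diet shared by the 3 groups that had it would give this. Both comparisons use the same normal libraries, so a trait of those libraries would give it as well, and the second is no independent support. For both arms against normal, 1 of 84 splits gave as many members lower (the real one, with 20 against at most 17 in the others). This count is for 1 list and was not adjusted for the other lists. In camera with an estimated correlation the list had an adjusted p of 0.0970. Chance is therefore made unlikely there but is not excluded. Time of sampling stays open. Per2, the clock gene of largest change, had 2.63 ± 0.75, and it is among the genes past the threshold in the authors' deposited table. In edgeR 0 of 18 clock genes passed over the list alone (3 at an unadjusted p under 0.05). For model against normal 10 splits are too few to exclude chance (18 members lower, at most 3 in the 9 other splits, 1 split as large).

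The Kupffer cell list was higher in arm D than in the model (median 1.19, and 0.74 without D.4), with D.4 and D.7 high and D.1 not. The mitochondrial share is argued against as the whole cause, since the median was 1.02 without M.6 and G.3 and 0.95 with the share as a covariate, at a median SE of 0.45 and 0.38 (0.47 with all libraries). Either way the count of members past the threshold fell from 9 to 0, without M.6 and G.3 mainly through smaller changes: 8 passed with the fold changes of all libraries put in place, 3 with their degrees of freedom and 0 with their SE. A lower share of hepatocyte RNA stays open: the Kupffer mean rose over the mean of stellate, cholangiocyte and B cell markers by 0.89 ± 0.58 (SE), under 2 standard errors, and hepatocyte markers, which would have to fall, had a median of 0.26 with 14 of 17 positive, but M.6 alone was low (10.36 log2 CPM against 11.20 to 11.29 in the other 5 libraries) and their high level would hide a small fall. More Kupffer cells or cell recruitment under didymin may account for the values as well, and of the 10 splits, too few to exclude chance, 2 gave at least 9 members, with 13 for the split of M.5, D.4 and D.7 against M.6, M2.1 and D.1.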

How the results depend on the processing

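The covariate, the runs without libraries of high mitochondrial share and the nuclear-coded genes were chosen after the data were seen; the other alternatives were not. No paired analysis was possible because no label ties a count column to a replicate number. Without M.6, G.3, M.5 and D.1 the model is M2.1 alone, with the spread taken from the other groups, so values of that setting against the model or of the model test 1 library and say nothing on stability.

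Genes past the threshold in edgeR were 0 in all 6 comparisons, at 607, 776, 287, 569, 423 and 883 genes with an unadjusted p under 0.05. Leaving out 1 library moved the latter to 285 to 2561, 318 to 1802, 232 to 921, 358 to 1605, 157 to 911 and 426 to 1214, and limma-voom gave 3585, 2479, 1584, 2255, 931 and 3088. With the mitochondrial share as a covariate these counts were 529, 1161, 678, 1092, 323 and 1077. Without M.6 and G.3 they were 657, 855, 584, 871, 242 and 1064. DESeq2 gave, without and with independent filtering, 41 and 42 for model against normal, 14 and 14 for arm D and 5 and 5 for arm G against model, 6 and 6 for both arms against model, 5 and 5 between the arms and 93 and 93 for both arms against normal. limma-voom with quality weights gave 6 for model against normal, 651 for both arms against normal and 0 otherwise; its weights were lowest for G.3 (0.181) and M2.1 (0.249). Without the filter on low counts edgeR called 3 for model against normal (Sqle, Tex13b and Tm7sf2), 1 between the arms (Bcl6) and 5 for both arms against normal. The last comparison gave 11 when fitted to its groups alone, 2 with the mitochondrial share as a covariate and 6 without M.6 and G.3. Model against normal gave 1 gene, Scd, without M.6 and G.3, and 1, Scd, with M2.1 as the only model library (without M.6, G.3, M.5 and D.1). Leaving out 1 library gave 0 to 6 for model against normal (1 without M.6, 6 without G.3), 0 to 0 for each arm against model, 0 to 1 for both arms against model (1 without D.7), 0 to 1 between the arms (1 without G.4), and 0 to 9 for both arms against normal (9 without M2.1, 7 without N.3, 2 without G.3). The cause of these differences was not tested.

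Gene lists past the threshold in camera were 8, 7, 10, 10, 4 and 18 in the same order and 0 in each with an estimated correlation. Leaving out 1 library gave 5 to 16 for model against normal (13 without N.3, 14 without M.5, 5 without M.6, 16 without M2.1), 6 to 13 for arm D (13 without M.5 or M.6), 5 to 15 for arm G (5 without M2.1), 8 to 15 for both arms against model, 2 to 14 between the arms (8 without D.1, 2 without D.4, 7 without G.1 or G.4, 14 without G.3) and 14 to 20 for both arms against normal. Without M.6 and G.3 there were 11 for arm D, 18 for arm G and 14 between the arms. Without M.6, G.3, M.5 and D.1, where M2.1 is the only model library, there were 15 for model against normal, 14 for arm D, 17 for arm G, 16 for both arms against model and 15 between the arms. With the covariate there were 16 for arm D and 11 between the arms. Other settings stayed within 1.5 times.

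Cholesterol members lower over the list alone stayed within 1.5 times of 18 (16 to 21) and of 19 (15 to 24) in all settings with at least 2 model libraries, and the first was 13 with M2.1 as the only one; leaving out 1 library gave 16 to 21 and 15 to 23. Kupffer members higher in arm D were 3 in a fit of the groups alone, 0 with the covariate, 0 without M.6 and G.3, 16 without M.6, G.3, M.5 and D.1 (D.4 and D.7 against M2.1 alone, a library of low Kupffer mean), and 0 to 13 without 1 library (0 without M.6, M2.1, D.4 or D.7). Immediate early members higher in arm G were 0 in a fit of the groups alone, 8 and 8 with DESeq2, 2 with limma-voom, 2 without M.6 and G.3, 2 without M.6, G.3, M.5 and D.1 (M2.1 alone again), and 0 to 8 without 1 library (0 without M.5, 1 without M.6 or G.1, 8 without G.4, 2 or 3 without 7 others). The difference in covariance that measures reversal ran from −0.35 to 0.10 for arm D (−0.35 without M2.1, 0.004 without M.5, 0.099 without M.6, 0.052 without M.6 and G.3) and from −0.21 to 0.12 for arm G (−0.21 without M2.1).

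Of 2666 values of single genes and list medians under alternatives, 2499 were scored as keeping their direction and side of the threshold. Another 160 came past it (52 of them with DESeq2 without independent filtering and 18 with limma-voom) and 7 changed sign. No gene passed in the main fit, so none could lose a call. List medians were scored on sign alone, a missing adjusted p counted as kept, and runs without libraries outside the compared groups were included. The 2499 are therefore no measure of stability. Fasn in model against normal ran from −0.86 to 0.016 without 1 library (the last without M.6) and was 0.020 without M.6 and G.3 and 0.27 without M.6, G.3, M.5 and D.1 (M2.1 alone). Col1a1 ran from −0.86 to 0.39 (the last without N.3) and was 0.46 with limma-voom. Srebf1 against the model ran from −1.70 to 0.11 in arm D and from −1.54 to 0.27 in arm G, both positive without M2.1. The cause of these turns was not tested. Depth limits genes near 1 CPM, above all in G.3 and M.6.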

Other observations

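The tests of genes and lists in this part were fixed before their values were seen, and the relations with the mitochondrial share were chosen after that share was seen. In both arms against normal, immune and blood cell markers were higher as lists. T and NK cell markers had a median log2 fold change of 1.09 with 16 of 18 positive, neutrophil markers 1.24 with 5 of 5, erythroid markers 1.14 with 7 of 7, B and plasma cell markers 1.04 with 9 of 9 and Kupffer cell markers 0.43 with 16 of 17. The inflammatory list had 0.55 with 22 of 31 positive, immediate early and heat shock genes 0.76 with 18 of 21, the cell cycle 0.64 with 21 of 24, interferon response genes 0.36 with 27 of 31, cytosolic ribosomal proteins 0.26 with 48 of 54 and pericentral hepatocyte markers 0.24 with 7 of 11. Lower were fatty acid oxidation and PPAR-alpha targets at −0.43 with 27 of 31 negative, lipogenic genes at −0.55 with 15 of 21, gluconeogenesis and glycolysis genes at −0.20 with 23 of 27, endoplasmic reticulum stress genes at −0.30 with 22 of 28, hepatocyte markers at −0.27 with 15 of 17 and sex-biased genes at −0.35 with 6 of 8. G.3 stood apart from the other 5 didymin libraries in several of these means. It was lowest in hepatocyte markers (10.01 log2 CPM against 11.23 to 11.50), endoplasmic reticulum stress (5.23 against 5.63 to 6.19) and fatty acid oxidation (6.58 against 7.02 to 7.66). It was highest in T and NK cell (2.20), B and plasma cell (2.45) and neutrophil markers (2.26). The adjusted p of the lists in camera ran from 4.36e-10 to 0.0458, and from 0.292 to 0.675 with an estimated correlation.

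Many lists did not pass for model against normal. Medians on the log2 scale were −0.35 for Kupffer cell markers, 0.43 for markers of lipid-associated macrophages, 0.43 for T and NK cell markers, 0.34 for B and plasma cell markers, 1.20 for neutrophil markers, 1.09 for erythroid markers, 0.61 for cholangiocyte markers, −0.13 for stellate cell markers, 0.39 for adipocyte markers and 0.61 for pancreas markers. Drug metabolism had −0.03, antioxidant enzymes 0.09, endoplasmic reticulum stress −0.22, interferon response −0.06, autophagy and lysosome −0.15, apoptosis and p53 targets 0.06, the circadian clock 0.09, lipid droplet genes −0.25, lipoprotein assembly −0.26, bile acid genes −0.05, extracellular matrix −0.05, pericentral markers 0.13, cytosolic ribosomal proteins 0.26 and oxidative phosphorylation 0.25. The inflammatory list had a median of 0.08 with a mean of −0.08, immediate early genes had 0.01 with a test in the negative direction, and drug metabolism and extracellular matrix had means of 0.02 and 0.04. These values do not tell fewer cells of a type from less RNA per cell.

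Over the 12 libraries, cytosolic ribosomal protein genes went up with the mitochondrial share by rank (rho = 0.762, adjusted permutation p = 0.0312) and less clearly by value (r = 0.515, adjusted p = 0.120, and 0.878 without G.3 and M.6). The cholesterol list went down with it (r = −0.64, adjusted permutation p = 0.0455; rho = −0.73, adjusted p = 0.0312), with r = −0.46 without G.3 and M.6. The Kupffer list had r = −0.42 (adjusted permutation p = 0.2001), rho = −0.33 (adjusted p = 0.298) and r = −0.11 without them. The groups are spread unevenly over the share, so these relations hold group differences too.

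Other splits of the same libraries gave large results. For model against normal 2 of 10 splits gave at least 607 genes at an unadjusted p under 0.05, and the highest other gave 3906 (N.1, N.2 and M2.1 against the rest, with 1442 past an adjusted p of 0.05). For arm D against model 2 of 10 gave at least 776 (highest other 2818, M.5, M.6 and D.1 against the rest), for arm G 8 of 10 gave at least 287 (highest other 4527, M.5, M.6 and G.3 against the rest, with 2416 past the adjusted threshold), and between the arms 6 of 10 gave at least 423 (highest other 799). For gene lists 8, 8, 8 and 10 of 10 splits gave at least the real 8, 7, 10 and 4, and the highest others were 17, 15, 18 and 18. With 10 splits the share cannot come under 0.05. With the 6 didymin libraries as 1 group, 37 of 84 splits gave at least 572 genes against the model (highest other 4867, M.5, M.6 and G.3 against the rest) and 53 of 84 at least 10 lists (highest other 19). Against normal, 16 of 84 gave at least 955 genes (highest other 2578) and 6 of 84 at least 18 lists (highest other 19). Chance is not excluded for these 4 counts. The splits with 3906, 2818, 4527 and 4867 genes part libraries of high from libraries of low mitochondrial share and called several times the real number, which points to a structure of the libraries other than their groups. Between the arms the 4 splits with D.1 and G.3 together gave 521 to 747 genes, nearer the real 423.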
